A study of Mus musculus with 6 samples.

How the data were processed

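RNA of embryonic mouse hearts was sequenced from 3 control and 3 double knockout libraries. Per the labels' protocols, RNA was isolated with a column kit and DNase, 500 ng of total RNA went into a stranded polyA library preparation, and reads were single-end of 75 bp. The submitters' processing notes name Trimmomatic, STAR 2.4.2a, featureCounts 1.5.0, DESeq2, DESeq and the mm10 genome build, with no role or order given; the gene annotation, the strand and multi-mapping settings and any filter are not given in the sources used here. The deposited table holds 1 column per library and 48709 genes with identifiers, symbols and biotypes.

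The values deposited by the authors are a score rather than a unit of counts: read counts scaled by 1 factor per library and rounded to whole numbers. This was read from the values. Whole numbers below 400 are missing at even spacing in control 2 (every 139), control 3 (every 21.3) and double knockout 1 (every 18.7), as rounding after scaling leaves them. Column totals lie between 19770390 and 20215282. The multiplier from reads to deposited values was estimated per library from that spacing, or by likelihood from how often each whole number occurs where none was missing, at 0.998, 1.01, 1.05, 1.06, 0.899 and 0.963 for controls 1 to 3 and knockouts 1 to 3. Dividing the deposited totals by it gave estimated depths of 20068989, 20054187, 19265217, 18760330, 21991535 and 20953978 reads. Rounding means that single reads cannot be recovered for each gene, so the count model planned for raw counts was replaced by its stated fallback. Scales are close to 1, so a value of 10 stands for about 10 reads, and genes with few reads carry the spread of small counts.

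Genes with a mean value of at least 1 in at least 1 genotype were tested (26747) with limma 3.58.1 in R 4.3.3, on log2(value + 1), with a variance trend and robust empirical Bayes moderation, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes on this scale understate the change of low genes. An adjusted p of a single gene comes from this fit unless another setting is named beside it. For 32 gene lists of 739 entries fixed before the data were examined, of which 738 had a gene in the table and 2 were matched by an older symbol, camera was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, both adjusted over the lists; none of the 12 lists that passed with the preset correlation passed with an estimated one. Fry was run as a second set test. Counts of list members use adjustment over all tested genes, and beside it adjustment over the list alone. Some genes sit in several lists.

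Genes to name were fixed by a rule before the data were examined: the 2 targeted genes; the 10 with the highest and the 10 with the lowest log2 fold change past the threshold whose genotypes do not overlap, with a mean of at least 50 in the higher genotype, leaving out predicted models and pseudogenes; the 4 members of each list with the lowest adjusted p among those past the threshold; and the 2 most abundant members of lists with none. Of the 96 genes besides the targeted ones, 82 passed, 48 of them also with each library left out in turn; 36 of the 82 calls were lost without the robust option; the other 34 are named with the libraries that decide their calls, and most of these without group means, a choice made after the values were seen. Of the genes the rule selects, 2 are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

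Coordinates, transcript length and GC content came from the GENCODE M21 annotation of GRCm38, the assembly of mm10; 99.3% of the table's identifiers were found in it. A trend with GC content and length of the longest transcript was estimated per library with natural splines of 5 degrees of freedom on protein-coding genes with a mean of at least 50, and subtracted, as an alternative. Other alternatives were rescaling, filters, pseudocounts, voom weights, moderation without the robust option, stricter thresholds, replicate number as a block and leaving out each library. Libraries were compared first: no pair held the same values, and Pearson's r within a genotype was at most 0.991. The labels call the controls littermates, but no source used here says that each library came from a separate animal, so p-values measure the spread between these libraries. The tests were tried on simulated values for the same genes with the estimated scales. In a simulation of the genotype comparison over 25760 genes with 200 changed, 55.2% of those changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 9.14% of calls were false; without the robust option the recovered shares were 38.8%, 80.6% and 97.0% and 1.37% of calls were false. Simulated unchanged lists reached p under 0.05 in 4.5% of 200 cases. Genes were simulated independently of each other and these lists drawn at random. The rate therefore does not cover lists whose members vary together, such as erythroid genes (estimated correlation 0.80). Figures were drawn with matplotlib 3.10.9. Mitochondrially encoded genes are listed at 0 in each library, and exon-level data, needed for splicing, were not used here.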

Results

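Hearts of C57BL6/J mouse embryos were profiled by polyA RNA sequencing in 2 genotypes, with 3 libraries each. Controls carried floxed alleles of Rbpms and Rbpms2, a pair of genes for RNA-binding proteins of the RRM family, and were littermates of the knockouts. Double knockouts carried the same floxed alleles plus a Cre transgene, for loss of both genes in cardiomyocytes, the contractile cells of the heart. The embryonic stage and the meaning of the library numbers were not given in the sources used here. Xist, expressed from the inactive X chromosome, was at 6 and 20 in control 3 and double knockout 3. It was at 19501 to 25229 in the other libraries. Eif2s3y, a Y-linked gene, was at 1207 and 1569 in control 3 and double knockout 3, and at 0 to 4 elsewhere. Libraries numbered 3 thus had a male pattern and the others a female one. Fits without both libraries numbered 3 compare female-pattern libraries alone. The deposited values summed to between 19770390 and 20215282 per library, and the reads behind them were estimated at 18760330 to 21991535. Between 26509 and 27680 genes had a value above 0 in a library. Values below are normalised read counts, as mean ± SD (n = 3 libraries per genotype), and log2 fold changes are knockout minus control on the log2(value + 1) scale, with SE where given. Pearson's r across genes was 0.983 to 0.991 between libraries of a genotype and 0.975 to 0.987 between genotypes.

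The comparison asks how the heart's transcripts differ between these genotypes. Cre went with the knockout group and no group had Cre alone. Effects of Cre itself therefore cannot be told apart from those of losing the genes. Protein was not measured here. Both targeted genes were lower in each knockout library than in each control library. Rbpms (chromosome 8, 33782643 to 33929863, minus strand, mm10) fell from 3787 ± 210.5 to 697 ± 25.6, a log2 fold change of -2.44 ± 0.08 (limma adjusted p = 6.83e-13). Rbpms2 (chromosome 9, 65629648 to 65660528, plus strand, mm10) fell from 2577 ± 136 to 1454 ± 211, a log2 fold change of -0.83 ± 0.10 (limma adjusted p = 2.92e-05). The knockout libraries still held reads of both genes. Values are sums over all exons of a gene, the floxed exons were not given in the sources used here, and cells other than cardiomyocytes were part of the tissue, so the values do not measure the share of alleles deleted. Without both libraries numbered 3, the Rbpms2 difference was -0.79 (adjusted p = 0.142).

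**Figure D1:**
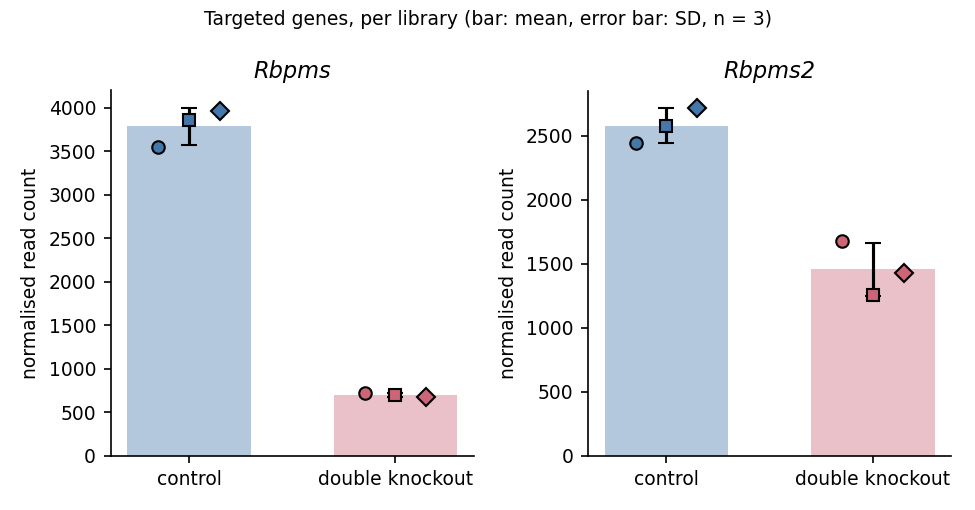
Normalised read counts of Rbpms (left) and Rbpms2 (right) by genotype; bars are means, error bars SD, and circles, squares and diamonds libraries 1, 2 and 3. The knockout libraries lie between 670 and 721 for Rbpms and between 1257 and 1676 for Rbpms2, below every control library.

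Among 26747 genes tested, 1299 differed between genotypes at an adjusted p under 0.05 (limma): 618 were higher and 681 lower in the knockout. Of these, 503 higher and 626 lower genes were annotated as protein-coding, and 146 higher and 122 lower genes differed by 2-fold or more. The groups did not overlap in 1295 of the 1299 genes; they did not overlap in 21.7% of all tested genes, where chance gives 10%. The counts rested on the moderation of variances and on single libraries: without the robust option 144 genes were higher and 206 lower, and without control 1, control 3 or double knockout 3 the totals were 481, 420 and 496. Of the 82 calls among genes selected for naming, 36 were lost without the robust option, 6 of them calls that held with each library left out: Actc1 (adjusted p = 0.0835), Jph2 (adjusted p = 0.0501), Cacna1d (adjusted p = 0.0635), Jag1 (adjusted p = 0.0661), Ckm (adjusted p = 0.0523) and Myl7 (adjusted p = 0.0669). Without both libraries numbered 3, 14 genes were higher and 24 lower. Libraries also differed in how expression followed GC content: Spearman's rho across genes between a gene's deviation and its GC content was 0.28, 0.22 and 0.40 in controls 1 to 3, and 0.13, -0.18 and -0.59 in knockouts 1 to 3. Each control lay above each knockout, so the trend was confounded with genotype, and it also varied within a genotype.

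The genes with the greatest rises included Ifi44, an interferon-induced gene, which rose from 3.67 ± 1.53 to 68.7 ± 17.01 (3.93, adjusted p = 3.16e-07). Unc13c, a synaptic vesicle priming factor, rose from 135 ± 4.62 to 621 ± 85.2 (2.19, adjusted p = 6.82e-10). Napb, a SNAP protein of vesicle fusion, rose from 104 ± 12.1 to 363 ± 41.6 (1.80, adjusted p = 9.33e-08). Dnah6, an axonemal dynein heavy chain, rose from 9 ± 3 to 66 ± 18.5 (2.75). The other genes of this set were the phosphodiesterase gene Pde4c (2.04), the collagen gene Col20a1 (1.81), Slitrk4 (1.66), the retinol carrier gene Rbp4 (1.59), the caveolar gene Murc (1.54) and Xirp2 (1.51), which encodes an actin-binding protein of muscle. Numbers in parentheses without a name are log2 fold changes. Murc rose from 55 ± 4.36 to 164 ± 38.2 and Xirp2 from 31.7 ± 4.04 to 94.7 ± 32.6. The genes with the greatest falls were led in abundance by Acta2 (smooth muscle actin), which fell from 26428 ± 1978 to 6030.3 ± 1183 (-2.15, adjusted p = 4.32e-07). Acta1 (skeletal muscle actin) fell from 6494 ± 574 to 1309 ± 330.0 (-2.34, adjusted p = 3.39e-05). Casq1, a calcium-binding protein of the sarcoplasmic reticulum, fell from 3621 ± 225 to 891 ± 74.2 (-2.02, adjusted p = 3.43e-11). Myl1, a myosin light chain of fast muscle, fell from 3781 ± 625 to 1033 ± 165 (-1.87). Kcnmb1, a subunit of the large-conductance potassium channel, fell from 426 ± 44.6 to 95.7 ± 10.5 (-2.14, adjusted p = 5.20e-09). Further genes of the set were B3gnt3 (-2.43), a glycosyltransferase gene, Cyb5r2 (-2.06), the potassium channel gene Kcnj6 (-1.85) and Ap3b2 (-2.43), an adaptor complex gene. The call of Ap3b2 was lost without control 1, 2 or 3 or double knockout 3 and that of Slitrk4 without control 1, with adjusted p up to 0.102 for Ap3b2 and 0.0579 for Slitrk4.

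**Figure D2:**
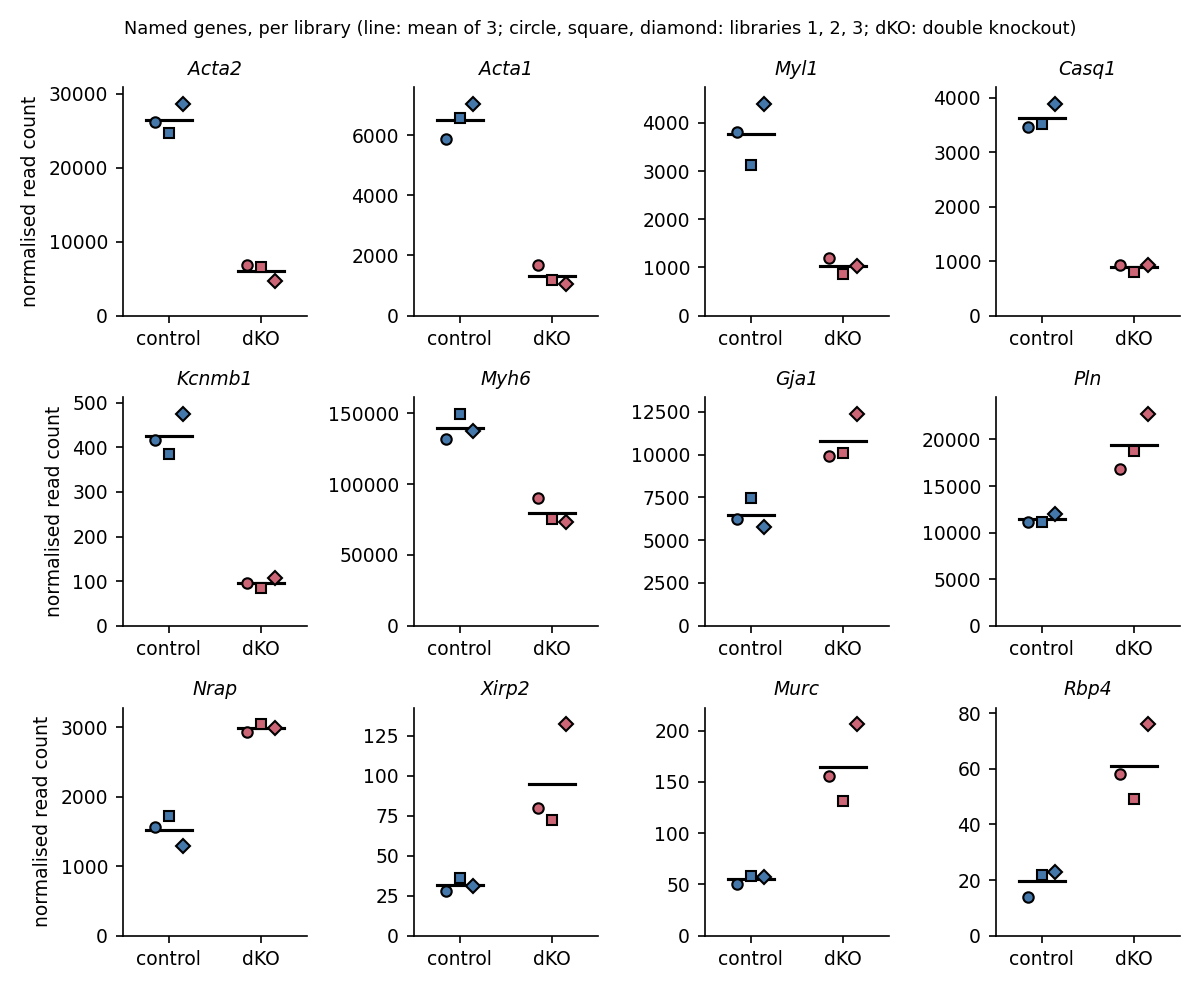
Normalised read counts of 12 named genes (vertical axes, linear and starting at 0) in control and double knockout (dKO) libraries; lines are means of 3, and circles, squares and diamonds libraries 1, 2 and 3. Acta2 lies between 24630 and 28547 in controls and between 4673 and 6843 in knockouts, and the genotypes do not overlap for any gene shown.

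Genes of the smooth muscle contractile apparatus were mostly lower. In this list 2 of 20 measured members rose and 8 fell (2 and 9 adjusted over the list alone). The median log2 fold change was -0.46 (camera adjusted p = 3.11e-05; adjusted p = 0.158 with an estimated correlation). Besides Acta2 and Kcnmb1, Myl9, the regulatory light chain of smooth muscle myosin, fell from 16825 ± 821 to 7109 ± 712 (-1.25, adjusted p = 4.42e-08). The riser named by the rule was Pln, phospholamban, an inhibitor of the calcium pump that cardiomyocytes also express. It rose from 11447 ± 522 to 19427 ± 2994 (0.75, adjusted p = 9.36e-05). Myh11, the smooth muscle myosin heavy chain, chosen after its values were seen, had 19.7 ± 6.51 in controls and 12 ± 1 in knockouts (adjusted p = 0.3004). Of the skeletal muscle list, 1 of 19 measured members rose and 6 fell (2 and 6 adjusted over the list alone). The list as a whole did not pass the set test (camera adjusted p = 0.125; adjusted p = 0.406 with an estimated correlation). Its members Mylpf, a fast-muscle myosin light chain (-1.04, adjusted p = 0.000135), and Ckm, muscle creatine kinase (-1.59, adjusted p = 0.000821), fell along with Acta1 and Myl1. The set test of the smooth muscle list also passed with each library left out, with adjusted p up to 0.00171, and with the GC and length trend of each library removed (adjusted p = 6.08e-06).

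Sarcomere genes of the heart moved in both directions. In that list 3 of 36 measured members rose and 6 fell (4 and 10 adjusted over the list alone), and the set test was not passed (camera adjusted p = 0.152; adjusted p = 0.406 with an estimated correlation), while fry gave a lower list (adjusted p = 0.0219). Myh6, the alpha myosin heavy chain, fell from 139844 ± 8691 to 79505 ± 9261 (-0.82, adjusted p = 1.68e-05). Myh7, the beta chain, chosen after its values were seen, had 208894 ± 19217 in controls and 212619 ± 21445 in knockouts (0.02, adjusted p = 0.914). Actc1, cardiac actin, fell from 187753 ± 8243 to 130892 ± 5949 (-0.52, adjusted p = 0.000647). Myoz2, a Z-disc protein, rose from 1290.3 ± 60 to 1884 ± 181 (0.54, adjusted p = 0.00114). Of the 12 core cardiomyocyte genes, 1 rose (Pln) and 3 fell (Myh6, Actc1 and Myl7; 1 and 5 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0133; adjusted p = 0.196 with an estimated correlation). This set call was lost without control 3 or double knockout 2, with adjusted p up to 0.0886. In the list of fetal and stress genes 6 of 22 measured members rose and 5 fell (6 and 5 adjusted over the list alone), and its median of 0.12 and its mean of -0.03 differed in sign (camera adjusted p = 0.803; adjusted p = 0.845 with an estimated correlation). Nrap, which takes part in myofibril assembly, rose from 1524 ± 215 to 2986 ± 57.4 (0.98, adjusted p = 3.94e-06). Ctgf, a matricellular protein gene, rose from 1802 ± 136 to 2858 ± 349.6 (0.66, adjusted p = 0.000286). Mybphl, a myosin-binding protein gene, fell from 490.3 ± 68.5 to 175 ± 39.6 (-1.50, adjusted p = 5.01e-05).

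Atrial genes were lower as a group. Of that list, 0 of 18 measured members rose and 7 fell (2 and 11 adjusted over the list alone). The median was -0.43 (camera adjusted p = 0.000392; adjusted p = 0.196 with an estimated correlation). Myl7, the atrial regulatory myosin light chain, fell from 24294 ± 4011 to 14533 ± 1901 (-0.74, adjusted p = 0.00226). Kcnj5, a subunit of the acetylcholine-activated potassium channel, fell from 2699.7 ± 92.5 to 1536 ± 216 (-0.82, adjusted p = 2.60e-05). Stard10, a lipid transfer protein gene, fell from 287 ± 52.05 to 171 ± 10.4 (-0.73), a call lost without control 3 (adjusted p = 0.0511). Ventricular genes did not move as a group: 1 of 14 measured members rose and 2 fell (4 and 4 adjusted over the list alone). The median was 0.03 (camera adjusted p = 0.811; adjusted p = 0.918 with an estimated correlation). The riser was Gja1, connexin 43. It rose from 6495 ± 874 to 10799 ± 1349.6 (0.73, adjusted p = 0.000339). Fhl2 (-0.38) and Hand1 (-0.36) fell, and each of these calls was lost when at least 1 library was left out (control 1, control 3, double knockout 2 or double knockout 3 for both, double knockout 1 also for Hand1), with adjusted p up to 0.164 for Fhl2 and 0.269 for Hand1. How much of each heart's atria and ventricles went into a library was not given in the sources used here.

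Ion channel and conduction genes were more often lower than higher. Of that list, 1 of 28 measured members rose and 6 fell (2 and 9 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.00874; adjusted p = 0.406 with an estimated correlation). Scn4b, a sodium channel subunit gene, fell from 118 ± 14.01 to 35 ± 11.8 (-1.76, adjusted p = 4.57e-05). Kcnk3, a background potassium channel gene, fell from 1409 ± 107 to 725 ± 140.3 (-0.97, adjusted p = 0.000298), as did Kcnj5; Gja1 rose. The set call was lost without control 2 (adjusted p = 0.0750) and with fry (adjusted p = 0.0782). Calcium-handling genes changed in both directions: 5 of 28 measured members rose and 5 fell (8 and 7 adjusted over the list alone). The median was 0.07 against a mean of -0.03 (camera adjusted p = 0.737; adjusted p = 0.825 with an estimated correlation). Besides Casq1 and Pln, Jph2, which tethers the sarcoplasmic reticulum to the plasma membrane, fell from 5820 ± 321 to 3929.7 ± 508 (-0.57, adjusted p = 0.00103). The calcium channel gene Cacna1d fell from 793 ± 86.9 to 467 ± 93.5 (-0.78, adjusted p = 0.00173).

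Genes of glycolysis and of the response to low oxygen were lower throughout most of the list. Here 0 of 30 measured members rose and 15 fell (0 and 19 adjusted over the list alone). The median was -0.34 (camera adjusted p = 1.17e-12; adjusted p = 0.196 with an estimated correlation), and 27 of 30 members lay below 0. The glycolytic enzyme genes Pfkl (from 6794 ± 94.4 to 3660.3 ± 562, -0.90, adjusted p = 9.30e-06), Eno1 (from 30962 ± 952 to 18164 ± 2477, -0.78, adjusted p = 4.48e-05) and Pgam1 (from 17152 ± 947 to 11477 ± 827, -0.58, adjusted p = 0.000329) fell. Car9, a carbonic anhydrase induced by low oxygen, fell from 83 ± 10.6 to 32 ± 5.196 (-1.35, adjusted p = 0.000418). With the GC and length trend removed, 14 members fell and none rose (camera adjusted p = 3.57e-13). Among nuclear-encoded genes of oxidative phosphorylation and the citric acid cycle, 0 of 34 measured members rose and 6 fell (0 and 9 adjusted over the list alone). All 34 lay below 0. The median was -0.18 (camera adjusted p = 1.47e-08; adjusted p = 0.406 with an estimated correlation). This set call was lost with fry (adjusted p = 0.119), while 13 members fell with the GC and length trend removed. Cyc1 (-0.45), Ogdh (-0.49), Cox7a1 (-0.43) and Uqcrc1 (-0.33) fell, but each of these calls was lost without control 1, control 3 or double knockout 3, and for some also without control 2 (Ogdh), double knockout 1 (Cox7a1) or double knockout 2 (Uqcrc1), with adjusted p up to 0.0732 for Cyc1, 0.127 for Ogdh, 0.264 for Cox7a1 and 0.222 for Uqcrc1. Fatty acid oxidation genes did not move as a group: 2 of 30 measured members rose and 1 fell (3 and 2 adjusted over the list alone). The median was 0.07 (camera adjusted p = 0.318; adjusted p = 0.656 with an estimated correlation). With the GC and length trend removed 6 members rose and 1 fell. Its risers before that were genes of fatty acid supply: Cd36, a fatty acid transporter, rose from 867 ± 31.95 to 1400.3 ± 136 (0.69, adjusted p = 0.000113). Lpl, lipoprotein lipase, rose from 4546 ± 634 to 7848 ± 788 (0.79, adjusted p = 0.000135). Acads, a dehydrogenase of the pathway, fell by 0.46 on the log2 scale, a call lost without control 1, control 3, double knockout 2 or double knockout 3 (adjusted p up to 0.181).

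Most cell division genes lay slightly below 0, and few passed singly. For mitosis and cytokinesis, 0 of 32 measured members rose and 3 fell (0 and 4 adjusted over the list alone), and 26 lay below 0. The median was -0.13 (camera adjusted p = 2.70e-05; adjusted p = 0.158 with an estimated correlation). With the GC and length trend removed, 9 members fell and 0 rose. Bub1b, a kinase of the spindle checkpoint, fell from 3219.7 ± 102 to 2409 ± 84.7 (-0.42, adjusted p = 0.00435). Plk1 (-0.32) and Kif20a (-0.32) fell with calls that were lost without control 1, control 3 or double knockout 3, and also without control 2 or double knockout 2 (Plk1) or double knockout 1 (Kif20a), with adjusted p up to 0.229 for Plk1 and 0.270 for Kif20a. For DNA replication, 1 of 30 measured members rose and 1 fell (1 and 1 adjusted over the list alone), and 26 lay below 0. The median was -0.14 (camera adjusted p = 0.000165; adjusted p = 0.187 with an estimated correlation). The riser Hells, a chromatin remodeller (0.36), and the faller Ung, a uracil glycosylase (-0.33), both lost their calls without control 1, control 3, double knockout 2 or double knockout 3, and Ung also without control 2, with adjusted p up to 0.193 for Hells and 0.233 for Ung. With the GC and length trend removed, Hells was at 0.16 (adjusted p = 0.160), and 0 members of the list rose and 2 fell. Among cell cycle inhibitors and p53 targets, 6 of 26 measured members rose and 0 fell (7 and 1 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.00878; adjusted p = 0.196 with an estimated correlation). Eda2r, a p53 target, rose from 131 ± 13.9 to 209 ± 14.5 (0.68, adjusted p = 0.00519). Trp53inp1 (0.51) rose too, with a call lost without control 3 or double knockout 3, as did the kinase inhibitor genes Cdkn1b (0.40, lost without control 1, control 3 or double knockout 3) and Cdkn1a (0.40, lost in each case but without double knockout 3). Adjusted p reached 0.0678 for Trp53inp1, 0.111 for Cdkn1b and 0.128 for Cdkn1a. The set call was lost without double knockout 1 or 2 (adjusted p up to 0.0513).

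**Figure D3:**
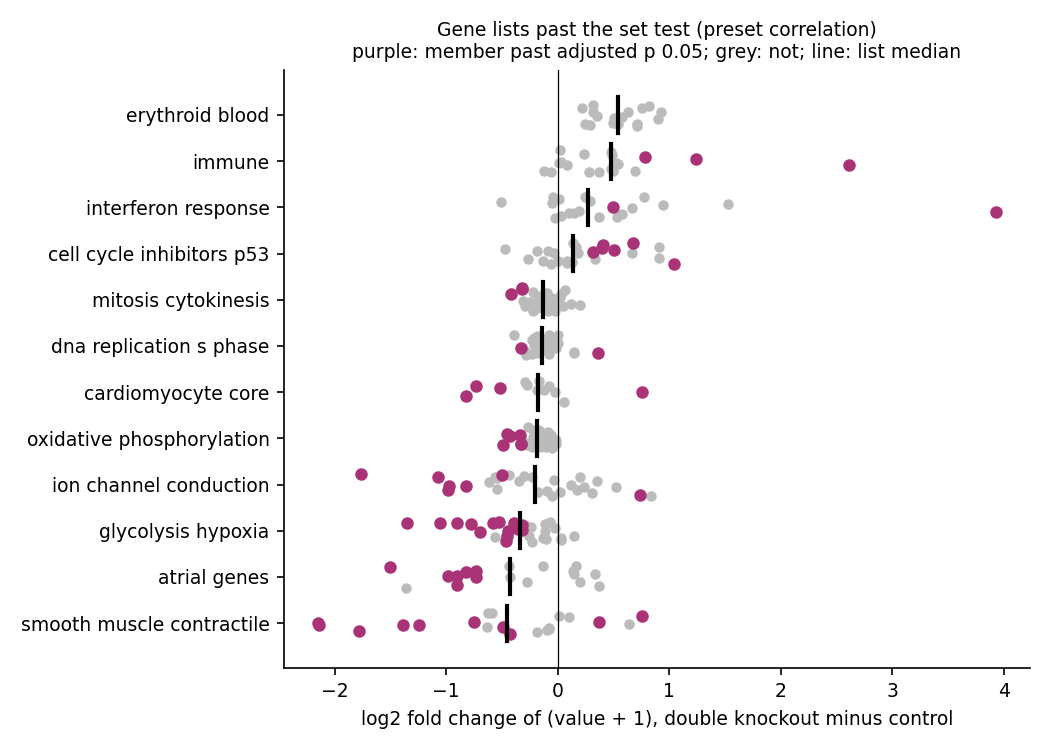
Log2 fold changes (horizontal axis, double knockout minus control, on values + 1) of the measured members of the 12 lists that passed camera with the preset correlation of 0.01. Purple points passed an adjusted p of 0.05, grey points did not, and black lines are list medians, which run from -0.46 for smooth muscle to 0.54 for erythroid genes.

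Regulators of the heart changed in both directions. Of the cardiac transcription factors, 1 of 32 measured members rose and 5 fell (5 and 8 adjusted over the list alone). The median was -0.04 (camera adjusted p = 0.153; adjusted p = 0.656 with an estimated correlation). With the GC and length trend removed this list was lower (adjusted p = 0.0413). Srf, serum response factor, a regulator of muscle and cytoskeletal genes, fell from 2743 ± 248 to 1745 ± 119.7 (-0.65, adjusted p = 0.0001998). Esrrg, an orphan nuclear receptor, rose from 1403 ± 85.3 to 1994 ± 196 (0.50, adjusted p = 0.00246). Nr2f1, a nuclear receptor of atrial identity, fell from 137 ± 30.6 to 72 ± 10 (-0.90), a call lost without control 3 or double knockout 3 (adjusted p up to 0.0691). In the list for trabeculation and compaction of the ventricular wall, 1 of 34 measured members rose and 3 fell (2 and 6 adjusted over the list alone). The median was 0.01 against a mean of -0.04 (camera adjusted p = 0.803; adjusted p = 0.918 with an estimated correlation). The Notch ligand gene Jag1 fell from 915 ± 89.1 to 596 ± 85.04 (-0.62, adjusted p = 0.00167). The growth factor gene Nrg1 (0.68) rose and Fkbp1a (-0.33) and Hey1 (-0.43) fell, and each lost its call in at least 4 of the 6 fits that left out 1 library (all but those without control 1 or 2 for Nrg1 and without control 2 or double knockout 2 for Fkbp1a, and all 6 for Hey1), with adjusted p up to 0.0823 for Nrg1, 0.233 for Fkbp1a and 0.312 for Hey1. Of the 26 muscle splicing regulators measured, 1 rose, Mbnl1 (0.43, lost without control 1, control 3 or double knockout 3), and 1 fell, Khdrbs3 (-0.45, lost without control 3), while 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.188; adjusted p = 0.779 with an estimated correlation). Adjusted p reached 0.138 for Mbnl1 and 0.0623 for Khdrbs3. Splicing itself cannot be read from gene totals.

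Markers of other cell types gave the following. For fibroblasts and mesenchyme, 0 of 16 measured members rose and 0 fell (0 and 0 adjusted over the list alone). The median was 0.05 (camera adjusted p = 0.737; adjusted p = 0.929 with an estimated correlation). The most abundant members were Col3a1, with 10942 ± 1524 in controls and 13267 ± 3831 in knockouts (adjusted p = 0.643), and Col1a2, with 4717 ± 674 in controls and 4385 ± 1393 in knockouts (adjusted p = 0.815). For endothelium, 1 of 20 measured members rose and 0 fell (3 and 1 adjusted over the list alone). The median was 0.07 (camera adjusted p = 0.137; adjusted p = 0.825 with an estimated correlation), and the list was higher with the GC and length trend removed (adjusted p = 0.00549). The riser was the sialomucin gene Emcn (0.38), whose call was kept only without double knockout 1 (adjusted p up to 0.203). For endocardium, 0 of 11 measured members rose and 0 fell (0 and 0 adjusted over the list alone). The median was -0.06 (camera adjusted p = 0.641; adjusted p = 0.825 with an estimated correlation). Cgnl1 had 8251 ± 642 in controls and 7906 ± 445 in knockouts (adjusted p = 0.750) and Npr3 4522 ± 593 in controls and 5024 ± 724 in knockouts (adjusted p = 0.517). For epicardium, 3 of 12 measured members rose and 1 fell (4 and 3 adjusted over the list alone). The median was -0.09 against a mean of 0.13 (camera adjusted p = 0.870; adjusted p = 0.937 with an estimated correlation). Krt19, a keratin gene, rose from 949 ± 95.2 to 1395 ± 33.3 (0.56, adjusted p = 0.000859). Muc16 (0.92), Krt8 (0.53) and Lrrn4 (-0.39) also passed. Their calls were lost without control 1 or control 3, and also without double knockout 2 or 3 (Muc16), control 2, double knockout 1 or double knockout 2 (Krt8), or control 2, double knockout 1 or double knockout 3 (Lrrn4), with adjusted p up to 0.103 for Muc16, 0.172 for Krt8 and 0.169 for Lrrn4. For neural and neural crest cells, 0 of 15 measured members rose and 0 fell (0 and 2 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.125; adjusted p = 0.483 with an estimated correlation). Tubb3 was at 133 ± 20.2 in controls and 103 ± 53.1 in knockouts (adjusted p = 0.578). For liver and lung, as neighbouring tissues, 0 of 9 measured members rose and 0 fell (0 and 0 adjusted over the list alone). The median was 0.43 (camera adjusted p = 0.508; adjusted p = 0.698 with an estimated correlation). Apoa2 was at 19.3 ± 1.15 in controls and 20.3 ± 3.06 in knockouts (adjusted p = 0.928) and Ttr at 10.3 ± 3.06 in controls and 10 ± 2.65 in knockouts (adjusted p = 0.974).

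Blood and immune genes were higher as lists with camera, and not with fry (adjusted p = 0.372 for erythroid, 0.0599 for immune and 0.176 for interferon genes). None of 17 measured erythroid genes passed singly (0 adjusted over the list alone), while all 17 lay above 0, with a median of 0.54 (camera adjusted p = 0.00132; adjusted p = 0.656 with an estimated correlation). Hbb-y, an embryonic globin gene, had 45302 ± 20439 in controls and 63244 ± 11564 in knockouts (adjusted p = 0.564). Hba-a1, an alpha globin gene with a near-identical copy, had 20481 ± 10015 in controls and 26741 ± 4843 in knockouts (adjusted p = 0.642). Hemoglobin genes took 0.324%, 0.604% and 0.899% of the deposited total in controls 1 to 3 and 0.699%, 0.803% and 0.94% in knockouts 1 to 3. The set call was lost without control 1 or double knockout 3 (adjusted p up to 0.149). In the immune list 3 of 20 measured members rose and 0 fell (3 and 0 adjusted over the list alone). The median was 0.48 (camera adjusted p = 0.00256; adjusted p = 0.379 with an estimated correlation). Ptprc, the leukocyte antigen CD45, rose from 13 ± 1.73 to 32 ± 2.65 (1.24, adjusted p = 0.00910), a call lost without control 3 or double knockout 3. The fractalkine receptor gene Cx3cr1 (0.78) and Cd14 (2.62), which lies near 0 in controls at 0.667 ± 1.15, also passed, but kept their calls only without control 2 or, for Cx3cr1, double knockout 1, with adjusted p up to 0.0655 for Ptprc, 0.139 for Cx3cr1 and 0.122 for Cd14. In the interferon list 2 of 20 measured members rose and 0 fell (2 and 0 adjusted over the list alone), Ifi44 and Ifit2 (0.50) being the risers, with a median of 0.27 (camera adjusted p = 0.009999; adjusted p = 0.618 with an estimated correlation). This set call was lost without control 1, control 3, double knockout 1 or double knockout 2 (adjusted p up to 0.0699), and that of Ifit2 in each case but without control 2 (adjusted p up to 0.248).

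Further lists gave few changes. Of extracellular matrix genes, 1 of 30 measured members rose and 0 fell (1 and 0 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.197; adjusted p = 0.825 with an estimated correlation), and the list was higher with the GC and length trend removed (adjusted p = 0.0368). The riser was the collagen gene Col12a1 (0.59), whose call was lost without control 1, control 3, double knockout 1 or double knockout 3 (adjusted p up to 0.0787). Of genes of the integrated stress and unfolded protein responses, 0 of 28 measured members rose and 2 fell (0 and 2 adjusted over the list alone). The median was -0.05 (camera adjusted p = 0.111; adjusted p = 0.452 with an estimated correlation). Herpud1, of endoplasmic reticulum quality control, fell from 743 ± 11.2 to 534 ± 30.1 (-0.48, adjusted p = 0.00349), and Mthfd2 (-0.36) lost its call whichever library was left out (adjusted p up to 0.259). Of immediate early genes, 1 of 18 measured members rose and 0 fell (1 and 1 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.318; adjusted p = 0.779 with an estimated correlation), and the list was higher with the GC and length trend removed (adjusted p = 0.0361). The riser Btg2 (0.32) kept its call only without double knockout 1 (adjusted p up to 0.227). None of the 30 ribosomal protein genes passed (0 adjusted over the list alone; camera adjusted p = 0.0914; adjusted p = 0.825 with an estimated correlation). Rpl4 was at 23702 ± 1198 in controls and 23170.3 ± 283 in knockouts (adjusted p = 0.871) and Rplp0 at 24907 ± 1379 in controls and 21591 ± 1661 in knockouts (adjusted p = 0.191). None of the 6 sex-linked genes passed (0 adjusted over the list alone; camera adjusted p = 0.894; adjusted p = 0.929 with an estimated correlation). Xist, expressed from the inactive X chromosome, was at 19501 and 23548 in controls 1 and 2, 24658 and 25229 in knockouts 1 and 2, and 6 and 20 in control 3 and knockout 3, which were the libraries with Eif2s3y, a Y-linked gene, at 1207 and 1569 (adjusted p = 0.944; 0.961 for Xist).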

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

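The GC and length correction (alone and with the replicate block), the fit without both libraries numbered 3, the Xist covariate and voom on estimated reads were chosen after seeing the data; the others before. The planned count models (edgeR and DESeq2, with TMM and other size factors of theirs) were not run because the deposited values are not counts; rescaling by median of ratios, upper quartile or equal totals, and voom, were run in their place. Genes past the threshold numbered 618 higher and 681 lower. They moved by over 1.5 times to 963 higher with no low-value filter, which tested 35139 genes. They likewise moved to 225 and 290 at an adjusted p of 0.01 and to 146 and 122 at 2-fold or more. Without robust moderation they moved to 144 and 206. In the simulated data the last setting moved calls from 175 to 146, of which 16 and 2 were false. That drop is smaller in proportion than the real one, so the simulation does not account for it. Leaving out 1 library gave 186 to 608 higher and 234 to 739 lower genes, lowest without control 3 (186 and 234), double knockout 3 (195 and 301) and control 1 (218 and 263), where 412, 463 and 468 of the genes called were among the 1299. Without both libraries numbered 3, 14 were higher and 24 lower, 36 of these 38 among the 1299. In simulated data the same reduction moved calls from 175 to 152. Recovery went from 55.2% to 31.3% of genes changed 1.5-fold, and from 98.5% to 97.0% of those changed 4-fold. Most real calls were below 2-fold, and the simulation held no GC or length trend between libraries. It therefore cannot tell how much of the drop is lost power, and the cause was not tested further. The other settings kept both counts within 1.5 times, and rescaling put the higher share between 46.9% and 55.0% against 47.6%. Removing the GC and length trend gave 662 higher and 869 lower genes, 1048 of them shared, and ended 10 calls of named genes (adjusted p = 0.151 for Hand1, 0.0778 for Nrg1, 0.0852 for Hey1, 0.160 for Hells, 0.0688 for Plk1, 0.0806 for Acads, 0.128 for Ogdh, 0.0621 for Cox7a1, 0.0526 for Emcn, 0.0956 for Ifit2). Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.05, 0.07 and 0.33, and not every library correlated best with its own number. With replicate number as a block, 674 genes were higher and 681 lower, 1109 shared, and the blocked fit with the GC and length trend removed gave 639 and 773. The block alone ended 7 calls of named genes and gained 1, and Xist level as a covariate ended 11. Rbpms stayed between -2.49 and -2.38 and past the threshold in each fit. Rbpms2 stayed between -0.94 and -0.73, past the threshold except without both libraries numbered 3 (-0.79, adjusted p = 0.142); the cause was not tested. Of the values for named genes, the alternatives chosen before gave 204 weaker and 1 stronger, the others 103 weaker, with 36 calls lost without robust moderation and 69 without both libraries numbered 3; for single lists these were 28 weaker and 7 stronger, and 3 and 8. No named gene or list changed direction past the threshold in any fit. Lists past the threshold numbered 12, 0 with an estimated correlation, 8 with fry (which ended 5 calls, with adjusted p in parentheses, for ion channel (0.0782), oxidative phosphorylation (0.119), erythroid (0.372), immune (0.0599), and interferon genes (0.176), and gained the sarcomere list (0.0219)), 16 with the GC and length trend removed (the 12 and, with their adjusted p, those for transcription factors, 0.0413, endothelium, 0.00549, extracellular matrix, 0.0368, and immediate early genes, 0.0361), 9 without both libraries numbered 3 (ending the calls for ion channel, adjusted p = 0.0678, interferon, adjusted p = 0.0586, and core cardiomyocyte genes, adjusted p = 0.130) and 10 to 14 with 1 library left out. The losses with an estimated correlation did not all need a higher correlation between members. For smooth muscle genes the estimate was 0.00996 against the preset 0.01, yet unadjusted camera p went from 3.89e-06 to 0.00988. It was below 0 for mitosis (-0.0032), p53 (-0.019) and core cardiomyocyte genes (-0.0035), but 0.80 for erythroid genes. When camera estimates the correlation, its degrees of freedom come from the few libraries and not from the number of genes. A loss in that setting alone therefore does not show that the members of a list vary together. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 1299; the highest other gave 1, and 10 splits are too few for a share under 0.05. Depth limits low genes: rounding to whole numbers blurs values of a few reads.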

Other observations

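The tests of the GC and length trend, of sarcomere and core cardiomyocyte against glycolysis genes, of shared reads and linked regions in gene clusters and of other splits were chosen after the results were seen; the lists of mural markers, SRF targets and HIF targets were fixed before their values were seen, except for the mural members Pdgfrb and Heyl, which other lists held. The 5 actin genes examined moved in opposite directions by class, an observation made after the values were seen. Actg2, an actin gene of the smooth muscle list, was not among them. The muscle actins Acta1, Acta2 and Actc1 fell, and their sum went from 220675 ± 9188 to 138231 ± 5511. The cytoplasmic actins rose: Actb from 17921 ± 1553 to 25240 ± 2744 (0.49, adjusted p = 0.00387) and Actg1 from 21321 ± 1702 to 33694 ± 2924 (0.66, adjusted p = 0.000143), and their sum went from 39242 ± 3071 to 58934 ± 5607. The sum of all 5 genes fell from 259918 ± 10301 to 197165 ± 9828, so the rise of the cytoplasmic genes is smaller than the fall of the muscle genes. Actin coding sequences are alike and how reads shared between them were counted is not given, so single values are uncertain. Rb1, a retinoblastoma gene that restrains cell cycle entry, rose from 330.3 ± 73.04 to 682 ± 168 (1.04, adjusted p = 0.0326) and was also chosen after its values were seen.

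Smooth muscle contractile genes were lower (median -0.46). A GC and length trend as the whole cause is argued against, since removing it left the median at -0.35 with a camera adjusted p of 6.08e-06; without that removal the call was lost with an estimated correlation (adjusted p = 0.158). For a smaller number of smooth muscle or other mural cells, 14 measured mural markers had a median of 0.14 (95% bootstrap interval over genes -0.17 to 0.31). A fall of these markers as large as that of the list (-0.46) lies outside this interval. The interval resamples genes, so it does not cover the spread between libraries. The set also mixes abundant markers, such as Mcam (5619 in controls) and Abcc9 (4230), with sparse ones such as Rgs5 (32.7). Which cells express them here was not tested, so fewer such cells as a cause cannot be excluded. The lower end of the interval also just passes the bound of -0.15 set for excluding a loss of such cells. In controls Acta2 was at 26428 and Myh11 at 19.7; which cells hold the Acta2 transcript was not tested. A candidate explanation by lower SRF activity (Srf -0.65) is not settled either: 24 SRF targets outside the lists had a median of -0.10 (95% interval -0.20 to 0.03; camera p = 0.0248, p = 0.365 with an estimated correlation), above the -0.2 set for it, with 4 that fell and 2 that rose (Actb and Actg1).

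Glycolysis and hypoxia genes were lower (median -0.34). Removing the GC and length trend left the median at -0.27 (camera adjusted p = 3.57e-13), which argues against that trend as the whole cause. Without that removal the call was lost with an estimated correlation (adjusted p = 0.196). A lower share of cardiomyocytes stays open. It would lower cardiomyocyte genes alike: the sarcomere median of -0.05 lay 0.29 above that of the glycolysis list (95% bootstrap interval 0.09 to 0.43), but that list has members going both ways and was lower with fry (adjusted p = 0.0219). The core cardiomyocyte list, with a median of -0.18 and 10 of 12 members below 0, lay 0.16 above it, with an interval of -0.10 to 0.33 that includes 0. A hypothesis of lower hypoxia-inducible factor (HIF) activity stays open: 24 HIF targets outside the list had a median of -0.15 (95% interval -0.19 to 0.00), below 0 but short of the -0.2 set in advance (camera p = 0.0130, p = 0.103 with an estimated correlation). Lower glycolytic expression as an effect of genotype remains untested beyond these lists.

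Called genes clustered in 2 of 504 windows of 5 Mb (hypergeometric test, adjusted p = 3.90e-05 and 0.00675). On chromosome 5, 15 of 58 genes tested were called, from 25919632 to 27501438 (mm10), all higher, with log2 fold changes of 1.47 to 2.52, with a median value of 6 in controls and 29 in knockouts; on chromosome 14, 12 of 60 were called, from 3332627 to 4875851, all lower, with log2 fold changes of -1.13 to -0.42. Both regions hold multi-copy families, and with the GC and length trend removed 24 of the 27 called genes passed in the same direction. On chromosome 14, with median values of 194 in controls and 137.5 in knockouts, 11 of 12 passed, which argues against that trend. On chromosome 5, 13 of 15 passed. The trend was fitted on protein-coding genes with a mean of at least 50, so its removal is uncertain for the lower values there. Reads shared between near-identical copies may make these calls depend on each other: within genotypes the median pairwise correlation of called genes was 0.67 on chromosome 5 and 0.83 on chromosome 14, where the highest of 1000 random sets of like abundance gave 0.28 and 0.41, though a common regulator would give the same. A difference of the linked chromosome region stays open. Of 93 named protein-coding neighbours within 5 Mb and with a mean of at least 50, 5 were called. Chromosome 14 had only 6 neighbours, 0 of them called. On chromosome 5, 5 of 87 were called (5.75%, Clopper-Pearson 95% interval 1.89% to 12.9%). The share over all mapped genes tested, 4.87%, includes low genes and is not a like comparison. Of 14016 genes with a mean of at least 50 in 1 genotype, 515 were called higher and 622 lower.

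Mitochondrially encoded genes are listed at 0 in each library, while nuclear pseudogenes that copy mitochondrial sequence are among the most abundant entries. How reads that match both were assigned is not given in the sources used here. The values of these copies may therefore hold reads of mitochondrial transcripts and cannot be read as expression of the pseudogenes. The 5 copies below were chosen after their values were seen. Gm28437 (chromosome 1, 24613189 to 24613971, mm10) went from 89799.7 ± 8911 to 133128 ± 27355 (0.55, adjusted p = 0.0332; 0.149 with the GC and length trend removed). Gm10925, next to it, went from 85127 ± 10064 to 125441 ± 25323 (0.55, adjusted p = 0.0383; 0.118 with the trend removed). The others did not pass: Gm28661 went from 108681 ± 12821 to 137648 ± 15916 (0.34, adjusted p = 0.0545), Gm29216 from 105626 ± 12405 to 125189 ± 16753 (0.24, adjusted p = 0.205) and Gm13340 from 75729 ± 9527 to 86092 ± 9948 (0.19, adjusted p = 0.338). Of 17516 genes with a summed value of at least 60, 56 had the same value as another gene in all 6 libraries. Leaving out predicted models and pseudogenes, 1079 of the 1299 called genes remain, 492 higher and 587 lower.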
